A study of Oryctolagus cuniculus with 14 samples.

How the data were processed

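Corneas had been kept in an RNA-stabilising solution overnight, RNA was extracted with a phenol-based reagent, and libraries were made from total RNA with a TruSeq RNA kit, per the labels' protocols. Sequencing was done on an Illumina NextSeq, per the series design text. The deposited values are raw counts, whole numbers per gene, with 1 file for each of the 14 libraries and no pooling of replicates. The submitters' processing notes name bcl2fastq 2.17, TopHat2 2.1.0, Cufflinks 2.0.2, DESeq and the genome build OryCun2.0. Which program counted the reads, its strand setting, how it treated reads with several matches and the annotation release were not given in the sources used here. Counts of genes that overlap, lie antisense to each other or have near-identical copies are therefore uncertain.

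All files held the same 23669 Ensembl rabbit gene IDs in the same order, with no summary lines. The deposited files do not pair the IDs with gene names. A table of 38822 RefSeq genes of assembly mOryCun1.1 was searched, and 0 of the 23669 IDs were found in it. The 40 gene lists fixed before the data were examined, the fixed panel of named genes and the requirement of a gene symbol could thus not be applied, and no check of GC content, gene length or other cell types was made. Coordinates were not used here. Of the tests set before the data were examined, those of each comparison over all genes were run as set, the rule for single genes was used without its requirement of a gene symbol, and the simulation for shared libraries was corrected once after its first output.

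Samples were grouped by the clinical status in the labels into impaired (n = 5), non-impaired (n = 5) and naive (n = 4). Replicate numbers only name libraries and pair nothing. The labels give no batch. No pair of libraries held near-identical counts: the lowest chi-square per degree of freedom of any pair was 14.6.

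Genes were kept by the default expression filter of edgeR 4.0.16 in R 4.3.3, which left 10048 genes holding 99.96% of all counts. Counts were scaled by TMM factors, which ranged from 0.924 to 1.058. All 3 groups entered 1 quasi-likelihood fit with robust dispersion and 11 residual degrees of freedom, and the common dispersion was 0.0602. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold change. Standard errors of log2 fold changes were taken from the fold change and the F statistic. CPM are counts relative to the TMM-scaled library size, and log2 CPM used a prior count of 2.

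The rule for single genes took, per comparison and direction, the 8 genes with the largest log2 fold change among those called, with a mean of at least 2 CPM in the higher group and no overlap between the libraries compared. Without gene names, IDs are printed only for the 2 genes that rose most and the 2 that fell most by this rule in impaired against naive corneas. This limit to 4 IDs was set after the data were examined. A fold against a group without counts is a lower bound on a floor of 3 counts over the group. The fitted fold change of such a gene depends on the prior count and is no bound. Floors cover counting error only.

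Library measures were compared by two-sided exact permutation tests over 126 or 252 splits of the libraries, adjusted over 9 tests. Comparisons that share a group were set against 20 simulations without effects, against independent lists, and against fits with the shared libraries divided between the comparisons.

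Alternatives were DESeq2 size factors, 2 other filters on low counts, DESeq2 1.42.0, limma 3.58.1 with voom and sample quality weights, fits on only the groups compared, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Added after the data were examined were fits without impaired 1 and naive 4, fits without the 10 most abundant genes, divided impaired and non-impaired libraries, and genes detected without thinning.

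The fits were tested on simulated data with 200 changed genes. Apart from these changes, each gene had the same mean and dispersion in all groups. A larger spread in impaired libraries and changes in many genes were therefore not covered. Against naive, edgeR recovered 69 of 100 genes changed 2-fold and 91 of 100 changed 4-fold for impaired corneas, with 4 false calls among 164 calls over 9945 genes. For non-impaired corneas it recovered 69 and 88, with 1 false call among 158 over 9925 genes. Between the exposed groups it recovered 67 and 92, with 5 false calls among 164 over 9945 genes. In the same order DESeq2 made 34 false calls among 200, 19 among 188 and 30 among 196, and limma voom made 5 among 163, 3 among 160 and 6 among 167.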

Results

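Gene expression was measured by RNA-seq in 14 corneas of New Zealand White rabbits. Eyes had been exposed to the vapor of sulfur mustard, an alkylating vesicant that injures the ocular surface. Corneas were taken 4 weeks later from 5 eyes scored as clinically impaired and 5 eyes scored as clinically non-impaired, beside 4 corneas from naive eyes. The series addresses the late corneal injury after such an exposure, and its design allows 3 comparisons: each exposed group against naive corneas, and the exposed groups against each other. The signs by which an eye was scored as impaired were not given in the sources used here. The labels do not say whether the corneas of a group came from separate rabbits, so p-values measure only the spread between these samples, which may be technical.

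Total counts per library lay between 12002876 (impaired 1) and 17488019 (naive 1), over 23669 rabbit gene IDs. Of these genes, 13971 had at least 1 count in any library and 10048 had enough counts to be tested. The deposited files do not pair the IDs with gene names, so gene groups are described here by how they moved across the 3 comparisons, and only 4 genes are given by ID. With every library thinned to 12002876 counts, 11749 ± 160 genes had at least 1 count in impaired corneas (SD, n = 5), 11641 ± 116 in non-impaired corneas (SD, n = 5) and 11373 ± 69.5 in naive corneas (SD, n = 4). Both exposed groups exceeded naive (exact permutation test, two-sided, p = 0.0159 each, adjusted p = 0.0204 over 9 tests), with every exposed library above every naive library. Without thinning, the excess of non-impaired over naive was 237 genes and did not pass (exact permutation test, p = 0.119). Impaired exceeded non-impaired by 108 genes, which was within the spread (exact permutation test, p = 0.254, adjusted p = 0.254).

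The most abundant gene was the same in all 14 libraries. It held 7.03% ± 0.12 of the counts in non-impaired corneas (SD, n = 5), 5.81% ± 0.36 in impaired corneas (SD, n = 5) and 4.93% ± 0.17 in naive corneas (SD, n = 4). The groups did not overlap, and the differences passed an exact permutation test (p = 0.00794 for non-impaired against naive and against impaired, the smallest p these splits allow; p = 0.0159 for impaired against naive; adjusted p = 0.0179, 0.0179 and 0.0204). The 10 most abundant genes of each library held 18.9% ± 0.60 in non-impaired, 15.5% ± 0.79 in impaired and 16.4% ± 0.56 in naive corneas. Here non-impaired exceeded both other groups (exact permutation test, p = 0.00794 each, adjusted p = 0.0179), and impaired and naive did not differ beyond their spread (p = 0.111, adjusted p = 0.125).

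The first principal component of log2 CPM took 45.6% of the variance and ordered the groups from naive (-65.9 to -47.1) through non-impaired (1.34 to 9.34) to impaired (30.7 to 66.1). The second took 18.4% and set the non-impaired corneas (28.6 to 34.1) above the impaired (-35.8 to 8.77) and naive corneas (-37.6 to 0.617). Impaired 1 had the highest value among impaired libraries on the second component, and naive 4 lay apart from naive 1 to 3 on both. Across genes, which are not independent replicates, the median Spearman correlation between libraries was 0.938 for impaired with naive, 0.956 for non-impaired with naive and 0.956 for impaired with non-impaired. Within groups it was 0.976 in impaired, 0.986 in non-impaired and 0.984 in naive corneas.

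**Figure D1:**
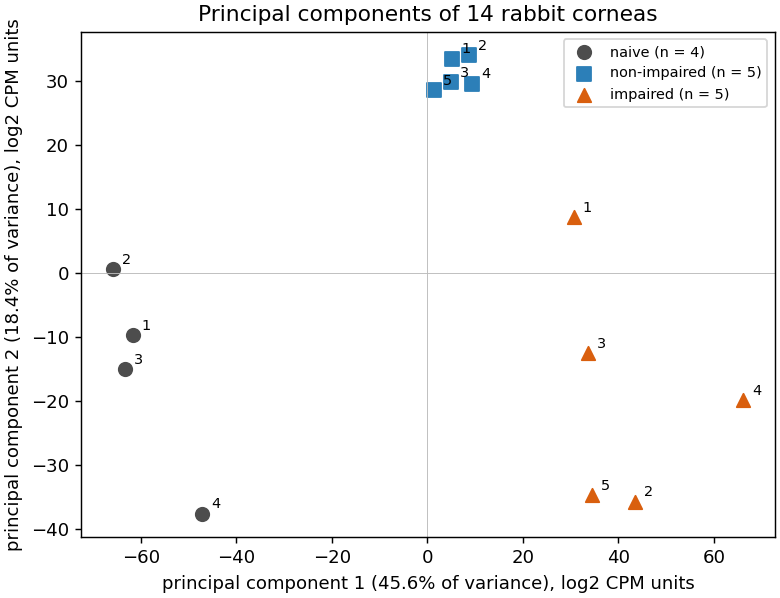
Principal components 1 (45.6% of variance) and 2 (18.4% of variance) of log2 CPM over the tested genes, with 1 point per cornea numbered by its replicate in its group. The 5 non-impaired corneas lie between naive and impaired on component 1 and at 28.6 to 34.1 on component 2, above all other libraries.

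Impaired corneas differed from naive corneas in 3572 of 10048 genes, of which 1989 rose and 1583 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The genes that rose moved further: 960 rose at least 2-fold and 355 at least 8-fold, whereas 332 fell at least 2-fold and 12 at least 8-fold. Their median log2 fold changes were 0.96 among risen and -0.57 among fallen genes, with a median of 0.01 over all tested genes. With only genes of at least 5 CPM in at least 4 libraries, the balance turned to 1525 risen and 1558 fallen genes. A fit on only these 2 groups called 2757 genes. The 8 genes that rose most by the fixed rule had a mean of 4.98 to 567 CPM in impaired corneas and 0 to 1.09 CPM in naive corneas, and 5 of them had no count in any naive library. In 6 of these 8 genes the impaired mean was more than 1.5 times that without the highest library, and the gene at 567 CPM (SD 1026, n = 5) had 109 ± 81.0 CPM without impaired 4 (SD, n = 4). Of these 8 genes, 5 were also higher in non-impaired than in naive corneas, and 5 were higher in impaired than in non-impaired corneas. The 8 genes that fell most had 3.38 to 62.4 CPM in naive and 0.154 to 7.17 CPM in impaired corneas, with log2 fold changes from -4.31 to -3.11. All 8 were also lower in non-impaired than in naive corneas, and 4 were lower in impaired than in non-impaired corneas.

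Among the risen genes, ENSOCUG00000028108 had no count in the 4 naive libraries and 26.9 ± 56.1 CPM in impaired corneas (SD, n = 5), at least 588-fold higher by mean CPM against a floor of 3 counts over the naive group (edgeR adjusted p = 0.0172). Impaired 4 held 1745 of its 1859 counts in impaired corneas. Without that library the mean was 1.81 ± 2.36 CPM (SD, n = 4), at least 39.6-fold higher (edgeR adjusted p = 0.00688, range 0.00688 to 0.0405 over the alternatives that tested the gene). ENSOCUG00000003958 likewise had no naive count and reached 8.30 ± 8.78 CPM in impaired corneas (SD, n = 5), at least 182-fold higher (edgeR adjusted p = 0.00387), and at least 107-fold higher without impaired 1, which held 279 of its 576 impaired counts. ENSOCUG00000017002 fell from 3.38 ± 0.48 CPM in naive (SD, n = 4) to 0.154 ± 0.255 CPM in impaired corneas (SD, n = 5), a log2 fold change of -4.31 (SE 0.71, edgeR adjusted p = 0.000463). This decrease rests on 223 naive and 12 impaired counts, 9 of them in impaired 5. Without that library the log2 fold change was -5.82, and the log2 ratio of the 3 remaining impaired counts to the naive counts was -6.01 (95% counting interval -8.30 to -4.44). ENSOCUG00000002244 fell from 6.43 ± 1.53 CPM (SD, n = 4) to 0.434 ± 0.211 CPM (SD, n = 5), a log2 fold change of -3.85 (SE 0.57, edgeR adjusted p = 0.000218).

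Over all tested genes, no impaired library overlapped any naive library in 2462, 24.5%, and no non-impaired library overlapped any naive library in 2545, 25.3%, where chance gives 1.59% each. The spread was largest in the impaired group, whose biological coefficient of variation was 29.8%, against 21.7% in naive and 20.2% in non-impaired corneas.

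Non-impaired corneas, scored free of clinical impairment, differed from naive corneas in 2287 genes, of which 1283 rose and 1004 fell (edgeR quasi-likelihood test, adjusted p below 0.05). Again more genes rose far than fell far: 614 rose at least 2-fold and 242 at least 8-fold, against 210 and 8 that fell as much. The median log2 fold change was 0.95 among risen and -0.55 among fallen genes. The 8 genes that rose most had a mean of 3.63 to 229 CPM in non-impaired corneas and 0 to 1.18 CPM in naive corneas, and in 2 of them the mean was more than 1.5 times that without non-impaired 1. All 8 were also higher in impaired than in naive corneas, and none of the 8 passed the test between the exposed groups. The 8 genes that fell most, with log2 fold changes from -4.02 to -2.41, had 3.35 to 139 CPM in naive and 0.221 to 16.3 CPM in non-impaired corneas. The gene at 139 CPM (SD 194, n = 4) had 43.2 ± 35.7 CPM in naive corneas without naive 4 (SD, n = 3). Of these, 6 were also lower in impaired than in naive corneas, and 2 were higher in impaired than in non-impaired corneas. Leaving out naive 3 reduced the genes that fell in non-impaired corneas from 1004 to 620, and limma voom called 1961 risen and 1754 fallen genes. In fits on only the 2 groups compared, non-impaired against naive had 2697 calls and impaired against naive 2757. The excess of 3572 over 2287 calls thus depended on the joint fit of all groups.

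Of the 4 genes given by ID, 3 also changed in non-impaired corneas. ENSOCUG00000003958 reached 1.60 ± 1.79 CPM (SD, n = 5) against no naive count, at least 35.0-fold higher (edgeR adjusted p = 0.0331), and at least 17.8-fold higher without non-impaired 1. This call was lost when any 1 of the 4 naive libraries or non-impaired 1 was left out, and without a filter on low counts (edgeR adjusted p = 0.0566 to 0.0645, lowest over the alternatives that tested the gene 5.11e-06). ENSOCUG00000017002 fell to 0.282 ± 0.160 CPM (SD, n = 5; log2 fold change -3.54, SE 0.66, edgeR adjusted p = 0.00198). ENSOCUG00000002244 fell to 1.38 ± 1.18 CPM (SD, n = 5; log2 fold change -2.18, SE 0.51, edgeR adjusted p = 0.00749). Non-impaired 5 held 55 of its 112 non-impaired counts, and without that library the mean was 0.909 ± 0.623 CPM (SD, n = 4) and the log2 fold change -2.76. ENSOCUG00000028108 stood at 1.07 ± 0.81 CPM (SD, n = 5), at least 23.5-fold above the naive floor, and did not pass (edgeR adjusted p = 0.251); of the alternatives that tested the gene it passed only with limma voom (adjusted p = 0.0361, range 0.0361 to 0.372).

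A group of 870 genes rose in both exposed groups, with median log2 fold changes of 1.70 in impaired and 1.49 in non-impaired corneas, and 404 genes fell in both (medians -0.67 and -0.59). Within the 870 genes, 703 did not pass the test between the exposed groups, 133 were higher in impaired than in non-impaired corneas and 34 were lower. Of the 404 genes, 349 did not pass that test, 43 were lower in impaired corneas and 12 were higher. Opposite directions from naive were found for 28 genes, of which 22 were higher in impaired and lower in non-impaired corneas and 6 the reverse. Leaving out naive 1 or naive 3 reduced the genes lower in both to 261 and 250, and limma voom raised them to 799.

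Both comparisons use the same 4 naive libraries. Independent lists of these sizes would share 254 risen and 158 fallen genes, and simulated groups without effects against the same naive libraries shared 0. As those simulations called at most 1 gene in either comparison, the 0 gives no chance value for shared calls. With the naive libraries split 2 and 2 between the comparisons, a median of 466 genes rose in both (460 to 500 over 6 assignments) and 165 fell in both (137 to 180), where independent lists of the divided sizes would share a median of 86.5 and 44.8. Across genes, which are not independent replicates, the log2 fold changes of the exposed groups correlated at r = 0.82, against a median of 0.55 in simulations and 0.718 with split naive libraries. This r was 0.733 without a filter on low counts and 0.773 with only genes of at least 5 CPM in at least 4 libraries. The covariance of the fold changes was 0.964, against 0.0458 in simulations and a median of 1.04 with split naive libraries. Both measures include genes without naive counts, whose fitted fold changes depend on the prior count. The 2 fold changes had the same sign in 66.0% of genes, against 68.0% to 69.9% in simulations and a median of 62.5% with split naive libraries. Agreement in sign over all genes was thus no more than the shared naive libraries alone gave in simulations.

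**Figure D2:**
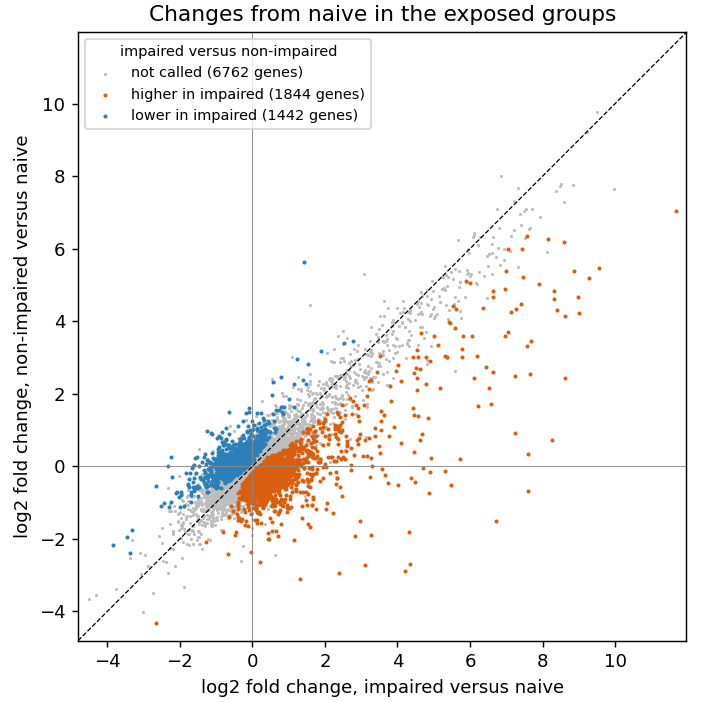
Log2 fold change against naive in impaired corneas (horizontal axis) and non-impaired corneas (vertical axis), 1 point per tested gene, with equal change on the dashed line. Colors give the test of impaired against non-impaired corneas, with 1844 genes higher and 1442 lower in impaired corneas. Fitted fold changes of genes without naive counts depend on the prior count.

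Impaired and non-impaired corneas, both from exposed eyes but scored differently in clinical status, differed in 3286 genes. Of these, 1844 were higher and 1442 lower in impaired corneas (edgeR quasi-likelihood test, adjusted p below 0.05). Whether the eyes of both groups received the same dose was not tested. At least 2-fold differences were found for 540 higher and 168 lower genes, and at least 8-fold differences for 70 higher genes and 1 lower gene. A group of 864 genes was higher in impaired corneas than in both other groups. In 709 of them non-impaired did not pass the test against naive, and their median log2 fold change was 0.75 for impaired against naive and 0.00 for non-impaired against naive. In the opposite direction, 760 genes were lower in impaired corneas than in both other groups. In 711 of those non-impaired did not pass the test against naive (medians -0.55 and -0.02). The 709 and 711 genes were selected by these same tests, so their medians follow in part from the selection. Without impaired 1 the balance turned to 1072 higher and 1170 lower genes, as it did with only genes of at least 5 CPM in at least 4 libraries (732 and 837) and without the 10 most abundant genes (819 and 839, a setting chosen after the data were seen). Without impaired 1 and naive 4, left out after their values were seen, the counts were 1395 higher and 1178 lower. Both comparisons share the impaired libraries: with these divided between the comparisons, a setting also chosen after the data were seen, a median of 417 genes was higher and 357 lower over 20 assignments. Independent lists would share 365 and 227 genes at the full sizes, and a median of 171 and 107 at the sizes of the divided fits.

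In 253 genes the non-impaired corneas were higher than both other groups, and in 446 they were lower. Of these, 6 were also among the 760 genes and 22 among the 864 genes. In 213 and 412 of them impaired did not pass the test against naive, with a median log2 fold change of non-impaired against naive of 0.53 and -0.51. These medians also follow in part from the selection. Without naive 3 these groups held 156 and 275 genes, and without naive 4 the lower group held 281. With limma voom, the higher group held 500 genes. With the non-impaired libraries divided between the comparisons, a setting chosen after the data were seen, the medians were 85 and 117 genes over 20 assignments, where independent lists of the divided sizes would share a median of 70.1 and 39.4. At the full sizes independent lists would share 184 in each direction.

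The 8 genes most elevated in impaired over non-impaired corneas had 2.48 to 105 CPM against 0 to 1.44 CPM, and in 1 of them, with 7.42 ± 9.60 CPM in impaired corneas (SD, n = 5), the mean was 3.25 ± 2.53 CPM without impaired 5 (SD, n = 4). All 8 were also higher in impaired than in naive corneas, and 1 of them was higher in non-impaired than in naive corneas. The 8 genes most reduced had 0.587 to 25.1 CPM against 2.24 to 98.9 CPM, with log2 fold changes from -2.51 to -1.71. Of these, 3 were also lower in impaired than in naive corneas, and 3 were higher in non-impaired than in naive corneas. Over all tested genes, the libraries of the exposed groups did not overlap in 2018, 20.1%, where chance gives 0.794%.

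Of the 4 genes given by ID, ENSOCUG00000002244 was lower in impaired than in non-impaired corneas (log2 fold change -1.67, SE 0.56, edgeR adjusted p = 0.0339). Its call was lost without impaired 2, impaired 4, non-impaired 1, non-impaired 2 or non-impaired 5 (edgeR adjusted p = 0.0793, 0.0712, 0.0548, 0.0560 and 0.120) and with limma voom (adjusted p = 0.172, range over the alternatives that tested the gene 0.0118 to 0.172). ENSOCUG00000028108 was higher (log2 fold change 4.62, SE 1.62, edgeR adjusted p = 0.0493), which rested on impaired 4: without that library the log2 fold change was 0.76 (edgeR adjusted p = 0.521). Leaving out impaired 3 or any 1 non-impaired library also ended this call (edgeR adjusted p from 0.0525 to 0.0986), as did a fit on only these groups, no filter on low counts and limma voom (adjusted p = 0.0518, 0.0997 and 0.389, range over the alternatives that tested the gene 0.0287 to 0.521). Not all of these fits lowered the log2 fold change, which was 5.20 without non-impaired 2. ENSOCUG00000003958 (log2 fold change 2.33, SE 0.96, edgeR adjusted p = 0.0861) did not pass, except with DESeq2 and without impaired 2 or non-impaired 1 (adjusted p = 0.0256, 0.0496 and 0.0367, range over the alternatives that tested the gene 0.0256 to 0.211). Its log2 fold change was 3.30 without non-impaired 1 and 1.55 without impaired 1. ENSOCUG00000017002 (log2 fold change -0.77, SE 0.81, edgeR adjusted p = 0.489) did not pass. Without impaired 5, with 3 impaired and 21 non-impaired counts, its log2 fold change was -2.28 (edgeR adjusted p = 0.0532), and the log2 ratio of these counts was -2.43 (95% counting interval -4.82 to -0.68).

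**Figure D3:**
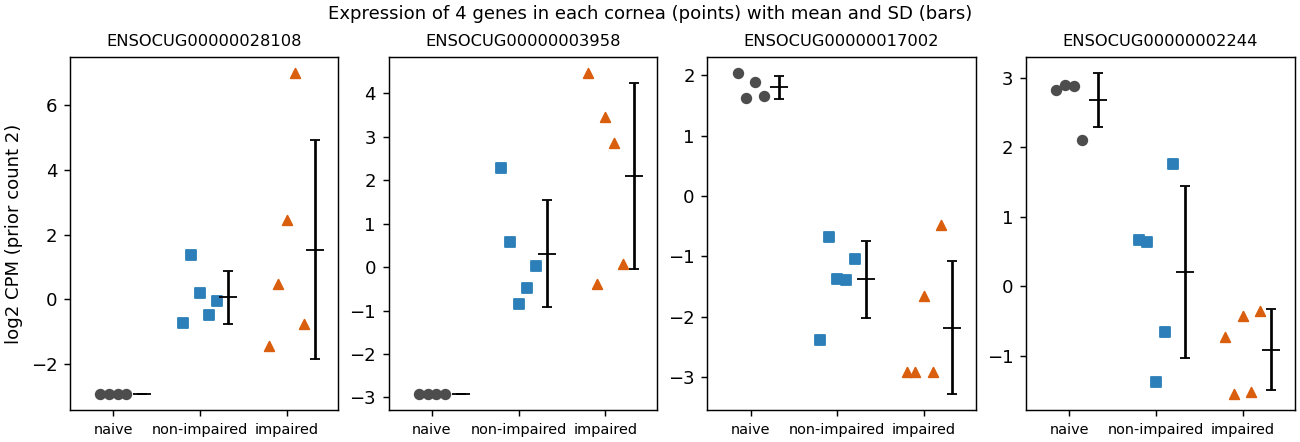
Expression of 4 genes as log2 CPM with a prior count of 2 (vertical axis, a separate scale per gene), 1 point per cornea in the naive (n = 4), non-impaired (n = 5) and impaired (n = 5) groups, with bars for the mean and SD. ENSOCUG00000028108 and ENSOCUG00000003958 have no count in any naive library, and ENSOCUG00000017002 and ENSOCUG00000002244 are lower in both exposed groups than in naive corneas.

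On a scale that set the mean of naive libraries at 0 and of impaired libraries at 1 over all tested genes, with each scored library left out of its own group mean, the non-impaired corneas scored 0.623 ± 0.029 (SD, n = 5). On the scale from non-impaired at 0 to impaired at 1, impaired 1 scored 0.502 and impaired 3 scored 0.778, and the other impaired libraries scored 0.949 to 1.07. Non-impaired libraries scored 0.0579 to 0.138 on that scale, and naive 4 scored 0.352, above the other naive libraries.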

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

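The tests on impaired 1 were set after that library had been seen to stand apart, though before their own values were known, and the fits without it and naive 4 were chosen only after the result was seen.

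Of 31 sets of values of 1 group, 6 had a library far from the rest of its group. The limits used mark about 1 set in 20 by chance if values are normally distributed. CPM of genes with few counts are skewed, and the genes given by ID were picked from these data for large fold changes. The number of marked sets is therefore no measure of an excess over chance. The gap to the nearest library is given as a fraction of the range of the group. Impaired 1 had 12002876 counts, below the next impaired library with 14863749 (fraction 0.724). Non-impaired 3 and non-impaired 4 had almost the same total as impaired 1, with 12028496 and 12026170 counts, and the labels give no batch. Naive 1 had 4.67% of its counts on the most abundant gene (95% Wilson interval 4.66 to 4.68, counting error only) against 5.0% in the nearest naive library (fraction 0.888). ENSOCUG00000028108 reached 127 CPM in impaired 4 against 5.29 CPM in the nearest impaired library (fraction 0.960), and 2.47 CPM in non-impaired 2 against 1.01 CPM (fraction 0.730). ENSOCUG00000003958 reached 4.74 CPM in non-impaired 1 against 1.36 CPM (fraction 0.783). ENSOCUG00000002244 stood at 4.15 CPM in naive 4 against 6.97 CPM (fraction 0.888).

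Chance assignment of libraries to groups was tested by drawing 100 of the 126 splits of the libraries in each comparison. For impaired against naive, 1 of 100 splits, the real one, gave as many as 3572 genes, and the highest other gave 3098. For non-impaired against naive, 1 of 100, the real one, gave as many as 2287, and the highest other gave 214. For impaired against non-impaired, 1 of 100, the real one, gave as many as 3286, and the highest other gave 1498. In all 3 comparisons the real grouping thus called more genes than any other split drawn. The real one was always among the 100, so 1 of 100 was the lowest share possible, and the splits not drawn were not seen. This count also takes the libraries as exchangeable, which the labels do not settle, so chance is not excluded by it. Some other splits also called many genes. Of those given next, all but the split with 917 genes differ from the real grouping by moving or exchanging 1 library. They keep most of the real grouping, so their calls do not show a separate structure of the samples. Grouped with the 4 naive libraries, impaired 1 gave the 3098 genes, impaired 3 gave 1611, impaired 5 gave 1365 and impaired 4 gave 3. Exchanging impaired 1 and naive 4 gave 2294, and impaired 1 and 3 grouped with naive 1 to 3 gave 917. The 1498 genes came from impaired 1 grouped with non-impaired 1, 2, 4 and 5, and impaired 1 with non-impaired 1, 2, 3 and 5 gave 1052.

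Impaired 1 resembled the non-impaired corneas more than the other impaired corneas did. A wrong label would place its score on the scale from non-impaired (0) to the other impaired corneas (1) within the non-impaired values, but it scored 0.502 against a highest non-impaired score of 0.138 (SD 0.035, n = 5). Its low total does not account for the resemblance either: with all libraries thinned to the same total, its mean correlation with non-impaired minus that with other impaired libraries was 0.00465, against -0.0244 to -0.0113 in the other impaired libraries. An admixture of RNA from another cornea was not tested. A milder or earlier state within the impaired group may be the source and remains a hypothesis, since the labels grade no severity.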

How the results depend on the processing

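The gene-list alternatives were not run, because no gene names could be assigned. No paired analysis was possible because the labels give no replicate numbers, and those used here follow accession order. Chosen only after the result was seen were the fits without impaired 1 and naive 4, those without the 10 most abundant genes, the divided exposed libraries and the unthinned gene numbers. No fold change of the 4 genes given by ID, no difference in a library measure and no correlation of fold changes changed sign under any alternative run. The signs of the other genes were not compared across alternatives. The balance of calls did turn: with at least 5 CPM in at least 4 libraries, impaired against naive had 1525 higher and 1558 lower genes, and impaired corneas lay above both other groups in 732 genes and below both in 837. The latter counts were 1072 and 1170 without impaired 1, and 819 and 839 without the 10 most abundant genes. Fits on only the groups compared called 2757 genes for impaired against naive, 2697 for non-impaired against naive and 3023 between the exposed groups. Against naive, the excess of calls in impaired over non-impaired corneas was thus small in these fits. Requiring an absolute log2 fold change of at least 1 left, by construction fewer, 960 higher and 332 lower genes for impaired against naive, 614 and 210 for non-impaired against naive, 540 and 168 between the exposed groups, and 516 higher and 105 lower in both exposed groups. With limma voom non-impaired against naive had 1961 higher and 1754 lower genes, and 799 genes were lower in both; the cause was not tested. Dividing the naive libraries, which leaves fewer samples per fit, gave 466 higher and 165 lower in both. With each library of the groups compared left out in turn, genes lower in non-impaired than naive ranged from 620 to 916, and genes lower in both from 250 to 475. Leaving out a library of the third group also moved the calls, and these fits are not in the ranges per comparison. Without impaired 1, non-impaired against naive had 2639 calls, against 2287 with all libraries. The other counts per comparison stayed within 1.5 times, at 1544 to 2177 higher and 1103 to 2032 lower for impaired against naive, 901 to 1184 higher for non-impaired against naive, and 1474 to 1945 higher and 1090 to 1890 lower between the exposed groups, with 654 to 898 higher in both. Without impaired 1 and naive 4 the 3 comparisons gave 2417 and 2039, 1236 and 996, and 2189 and 1803 higher and lower genes. DESeq2 kept 99.4% to 99.6% of the calls while calling more genes (3968, 2828 and 3722), and DESeq2 size factors kept 99.3% to 99.6%. Other settings kept fewer: 76.0% to 92.7% in fits on only the groups compared and 81.7% to 88.5% with the filter at 5 CPM. Without naive 3, 65.2% of the calls of non-impaired against naive were kept. Of the alternative values for the 4 genes given by ID, 162 kept their side of the threshold, 22 lost the call and 4 gained it; DESeq2 gave no adjusted p for ENSOCUG00000028108, the filter at 5 CPM removed all 4 genes, and the fits on only the groups compared lacked some of them. Few counts limit the fold changes of the fallen genes given by ID, with 12 and 32 impaired counts.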

Other observations

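The counts of near-silent genes, the wrong-label test of naive 4, the test of abundant genes and the tests of coincidence were chosen only after the result was seen. The test of a leading difference shared between corneas was set after naive 4 had been seen to stand apart, though before its own value was known.

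Genes that were near silent in naive corneas and present in every exposed cornea were counted. With fewer than 3 summed counts over the 4 naive libraries, 20 genes had at least 1 CPM in each of the 5 impaired libraries, and 13 genes had at least 1 CPM in each of the 5 non-impaired libraries. The reverse was not found by this rule: 0 genes near silent in impaired corneas, and 0 near silent in non-impaired corneas, were present in every naive library. Between the exposed groups the rule also gave 0 genes in each direction.

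Libraries of impaired corneas differed more from each other than those of the other groups did. Their mean distance to their own group, as 1 minus the mean correlation across genes, was 0.0263 ± 0.0042 (SD, n = 5), against 0.0149 ± 0.0015 in non-impaired (SD, n = 5) and 0.0159 ± 0.0042 in naive corneas (SD, n = 4; exact permutation test, two-sided, p = 0.00794 against each, the smallest p possible). The distances are not fully independent, since each uses the other libraries of its group. With any 1 library left out, the biological coefficient of variation was 27.6% to 31.4% in impaired corneas and at most 24.4% in the other groups.

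Naive 4 stood apart from naive 1 to 3, toward the impaired corneas. A wrong label does not account for this: of 26 genes near silent in naive 1 to 3 and present in all impaired libraries, 0% were at 1 CPM or more in naive 4. Its difference from naive 1 to 3 correlated across genes, which are not independent replicates, at r = 0.459 with the difference of impaired from non-impaired corneas, which rests on none of the same libraries, against -0.210 to 0.189 for naive 1, 2 and 3, each minus the other 2 of these. A leading difference between corneas that exposed and unexposed eyes share, such as in dissection or in the share of a tissue layer, might be a source, but the first components within naive and within impaired corneas correlated only at an absolute r of 0.294. That value lies between the limits set for and against it, with 4 naive libraries, so such a shared difference cannot be told apart from a separate change in that cornea. For the first components within naive and within non-impaired corneas the absolute r was 0.0457, which gave no sign that the non-impaired corneas share the naive component. Between the first components within impaired and within non-impaired corneas the absolute r was 0.345, larger than that of naive with impaired.

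In 699 genes the non-impaired corneas lay above or below both other groups. The 10 most abundant genes imply a log2 shift of 0.0589 in all other genes, below 0.373, the lower quartile of the changes. These genes were taken because they were called, which favors large changes, and TMM scaling is meant to remove a common shift. This comparison therefore cannot decide whether more counts on a few abundant genes played a part. Fits without the 10 most abundant genes kept 98.6% of all calls of non-impaired against naive and 97.5% of those between the exposed groups. Dividing the non-impaired libraries between the comparisons left 169 to 250 genes, but the simulations without effects called at most 1 gene per comparison, so the limit set against chance deviations of the shared libraries was met by construction, and how far they add to the 699 genes stays open. If every gene were equally likely to be called, unrelated changes that coincide would give as many genes as independent lists. For genes below both groups the divided libraries gave at least 1.80 times that number (median 2.88). For genes above both groups they gave as little as 1.04 times (median 1.20, SD 0.18 over 20 assignments), so this part cannot be told apart from coincidence. Whether genes were equally likely to be called was not tested, so the excess for genes below both groups does not exclude coincidence either.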
